A study of Homo sapiens with 6 samples.

How the data were processed

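Chromatin immunoprecipitation followed by sequencing was made by the submitters for H3K4me3 and H3K27me3, with an input sample per condition, in GATA2-positive endothelial cells derived from the established embryonic stem cell line H1. The 6 samples were grouped by the condition and antibody in their labels, which gave 4 mark libraries and 2 inputs. The inputs were not used here. The names of all 4 files give the opposite condition to the sample labels, and the series design text speaks of GATA2 reporter positive and negative cells where every sample label says GATA2 positive. Groups follow the sample labels, and the libraries are called by their labels throughout. The protocol in the labels names only H3K27me3 antibodies, while the antibody field names both marks.

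Each library had 1 deposited list of islands, which are enriched stretches merged from neighbouring windows. Per the submitters' processing notes, Bowtie2, SICER and deepTools were used and the builds hg38 and GRCh38 are named, with no role, order, version or setting. From the values, all island widths are multiples of 200 bp, and islands lie at least 400 bp apart for H3K4me3 and 800 bp apart for H3K27me3. The deposited score of each island was taken as −log10 of a false discovery rate within its library, because values in these lists run from just above 2 to 309 and then jump to 1000. The score is the authors', depends on depth and island width, and was used to rank or filter islands within a list, and scores of different libraries are not compared. Neither read counts per island nor library depth is given in the sources used here, so precision is that of the number of islands or genes, and exact Clopper-Pearson intervals at 95% cover counting error only. How often an island would be called again in another culture is not measured by any of these values.

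Deposited starts count from 0 and ends are inclusive, and coordinates are given counted from 1. Islands on chromosomes 1 to 22 and X were kept. Genes were taken from a RefSeq gene table of assembly GRCh38 patch 14, with 19974 protein-coding genes on these chromosomes. As a check of the build, H3K4me3 was called at 14050 genes in the library labelled Vc−, and at 2297 when gene ends were moved by 100 kb. The table gives the span of each gene without strand, exons or transcript starts, so a gene was called marked where an island overlapped by at least 1 bp the window of 1 kb on either side of either end of its span. This replaces a planned promoter at the 5′ end. It can count an island at the far end of a gene, and exonic, intronic and untranslated parts are not told apart. Planned comparisons of reads in regions called in both lists were not run, because the lists hold a score and no read count.

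Shared islands were those overlapping the other list by at least 1 bp, with the Jaccard index over base pairs. Widths were compared over islands that matched exactly 1 island in each direction. Gene lists were fixed before the data were examined, 14 by name with 263 members, all found in the gene table, and 9 by symbol pattern. For each list and mark, the net number (called in Vc+ alone minus Vc− alone, the opposite sign to the plan) was placed among 10000 random lists of protein-coding genes of the same size (seed 1). Matching on CpG content was planned and could not be done without a genome sequence, so these lists were unmatched. An added version drew them from genes with H3K4me3 in both conditions. The net over the 4 blood and endothelial lists together was computed after the lists had been seen.

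The rule for named genes was also fixed before. For each mark and direction, the genes called in 1 condition with no island of the mark within 10 kb of a gene end in the other were ranked by the score of their island, and the first 12 islands were named. Members of the blood regulator, blood cell marker, endothelial and arterial lists whose call differed were named too, with up to 3 of the differing members of the other lists taken by score from either library without reading that order as a result, GATA2 and RUNX1, and the 3 widest islands of each list. Genes outside that rule are said to be so. No test was made between conditions. Alternatives covered stricter island thresholds, equal island number or covered length, other overlap rules, windows of 2 kb and 500 bp, and long non-coding RNA genes. Others were added after the data were seen: ranking by score, leaving out islands within 5 Mb of the largest gene-free gap of each chromosome, a score of at least 10, and other choices of gene end.

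Interval code was checked against bedtools 2.31.1 and tested on simulated data: of 400 genes given a planted island in the H3K27me3 lists 396 (99.0%) were recovered over 19974 genes, and 400 of 400 in the H3K4me3 lists. Planted islands were centred on an end of genes without an island within 10 kb. Recovery therefore checks the code and does not measure how well real differences are found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.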

Results

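H3K27me3, the histone mark laid down by Polycomb repressive complex 2, and H3K4me3, the mark of active and poised promoters, were profiled by chromatin immunoprecipitation and sequencing in endothelial cells derived from the human embryonic stem cell line H1 and positive for GATA2, a transcription factor of blood and endothelial development. The cells were derived without or with Vc, which the series title gives as vitamin C, a cofactor of histone demethylases. The series holds 6 samples, 3 per condition, and 4 of them had an island list that was analysed: H3K27me3 and H3K4me3 in the condition labelled Vc−, and the same marks in the condition labelled Vc+. Each mark and condition had 1 library, so no replicate check, no test and no p-value across genes could be had, and every difference given is a difference between 2 libraries. On chromosomes 1 to 22 and X the lists held 8990 H3K27me3 islands in the library labelled Vc− and 9639 in the library labelled Vc+, and 22307 and 21991 H3K4me3 islands. The read depth of the libraries is unknown from these lists. The names of all 4 files give the opposite condition to the labels, so each direction holds for the libraries as labelled and would turn if the file names were right.

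The title names demethylation of H3K27 that depends on vitamin C on the way from endothelium to blood, and genes of these lineages were therefore examined for H3K27me3. The mark was called in the library labelled Vc+ alone at 4 of 26 blood regulators, and in the library labelled Vc− alone at none of them. These were IKZF1 and MYB, transcription factors of lymphoid and definitive blood development, LYL1, a basic helix-loop-helix factor of blood stem cells, and HHEX, a homeobox factor of early blood and endothelium. A further 7 blood regulators carried an H3K27me3 island in both conditions, among them GATA2, GFI1, MECOM and ERG. The other 15 had none within 1 kb of a gene end in either. RUNX1 was among these 15, although H3K27me3 islands lay inside the gene in both libraries. Of 20 endothelial genes, 3 were called in the library labelled Vc+ alone, 0 in the library labelled Vc− alone and 3 in both. The first 3 were SOX18, an endothelial transcription factor, CDH5, which encodes VE-cadherin, and VWF, which encodes von Willebrand factor. Read by the labels, H3K27me3 called at genes with Vc alone runs against the demethylation that the title names. Read by the file names, it would run with it.

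The islands at these genes were 1.60 to 5.80 kb wide. At IKZF1 (NCBI gene 10320, GRCh38 chromosome 7, 50303455 to 50405101) the H3K27me3 island of the library labelled Vc+ ran from 50301601 to 50305800, across the lower-coordinate end of the gene. The nearest island to a gene end in the other library was 526 kb away. At MYB (gene 4602, chromosome 6, 135181308 to 135219172) it ran from 135181801 to 135184000, inside the gene at its lower-coordinate end, with the nearest island of the other library 862 kb away. At LYL1 (gene 4066, chromosome 19, 13099033 to 13102858) it ran from 13098801 to 13102200 and covered most of the gene, and at SOX18 (gene 54345, chromosome 20, 64047582 to 64049639) from 64046401 to 64049000. The nearest islands of the other library were 35.2 kb and 33.6 kb from these genes. HHEX and VWF differed less clearly, because an island of the library labelled Vc− lay 1.15 kb from an end of HHEX and 1.08 kb from an end of VWF, just outside the 1 kb window.

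**Figure D1:**
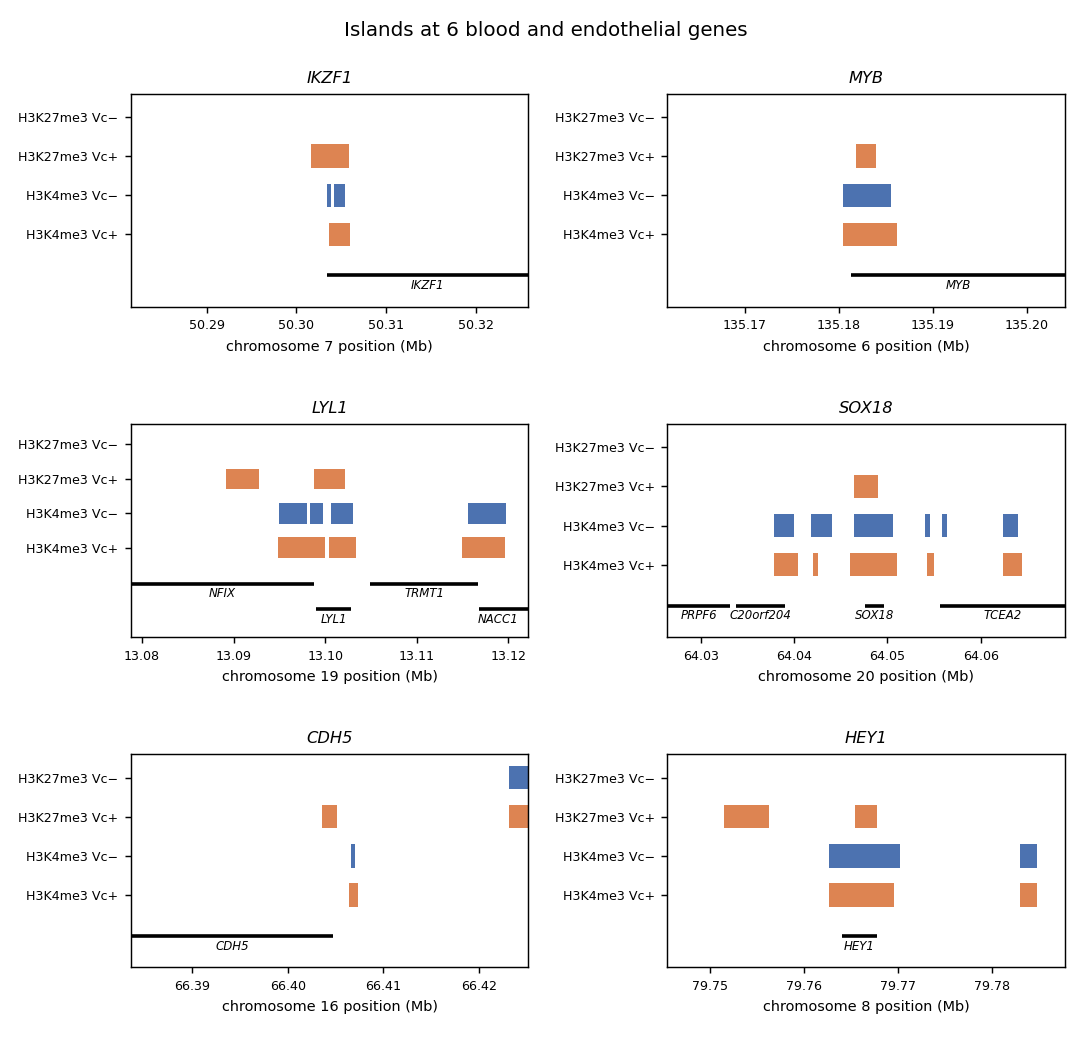
Islands of both marks in both conditions (colour) at IKZF1, MYB, LYL1, SOX18, CDH5 and HEY1, drawn to scale against the chromosome position in Mb, from 20 kb before to 20 kb after the H3K27me3 island of the library labelled Vc+, with protein-coding genes as black bars. An H3K27me3 island lies at each of the 6 genes in the library labelled Vc+, for example 4.20 kb at IKZF1 and 2.20 kb at MYB, and none lies within 1 kb of an end of these genes in the library labelled Vc−.

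Among 24 markers of blood cells H3K27me3 was called in the library labelled Vc+ alone at CD34, a surface protein of blood progenitors and endothelium, and at CD33, a sialic acid-binding protein of myeloid cells, in both at KIT alone, and in neither at 21. The islands at CD34 and CD33 scored only 3.66 and 4.22. Among 19 arterial and Notch genes, HEY1, a Notch target, was called in the library labelled Vc+ alone, 6 genes including DLL4, CXCR4 and UNC5B were called in both, and 12 in neither. Over the 4 lists together, 10 of 89 genes were called in the library labelled Vc+ alone, 0 in the library labelled Vc− alone and 17 in both. A net number of 4 or more was reached by 0.49% of 10000 random lists of 26 protein-coding genes for the blood regulators. The corresponding shares were 1.31% for the endothelial genes, 11.8% for the blood cell markers and 35.3% for the arterial and Notch genes. With random lists drawn from genes with H3K4me3 in both conditions, the blood regulators stayed low at 0.34%, the endothelial genes stood at 9.16% (a net of 2 over 18 genes) and the blood cell markers at 19.7%. These shares describe the libraries and are not p-values. H3K4me3 was present in both conditions at the same gene end for 7 of the 10 genes, and the calls at CDH5, VWF and CD33 lay at an end without it.

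**Figure D2:**
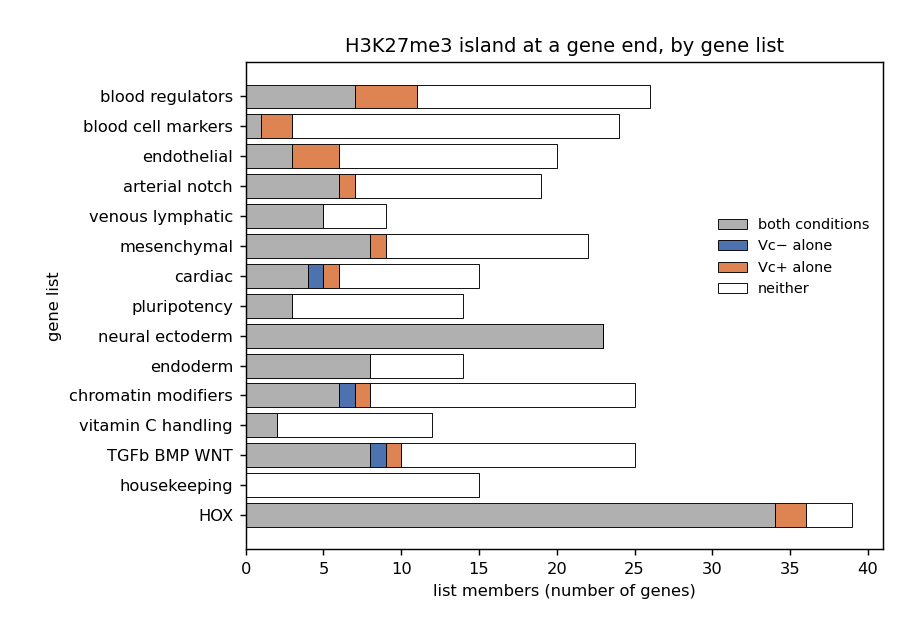
Number of genes in each of 15 lists (bars, horizontal axis) with an H3K27me3 island within 1 kb of a gene end in both conditions, in the library labelled Vc− alone, in the library labelled Vc+ alone, or in neither. Of the 26 blood regulators 4 are called in the library labelled Vc+ alone, and all 23 neural genes are called in both.

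Lists of other lineages gave few calls in 1 condition alone. All 23 neural ectoderm genes and 8 of 14 endoderm genes carried H3K27me3 in both conditions, and the venous and lymphatic list had 5 of 9, the pluripotency list 3 of 14 and the vitamin C handling list 2 of 12, each with none in 1 condition alone. In the mesenchymal list 8 of 22 genes were called in both and ZEB1, a driver of epithelial to mesenchymal transition, in the library labelled Vc+ alone. The cardiac list had 4 of 15 in both, with ISL1 in the library labelled Vc− alone and GATA5 in the library labelled Vc+ alone. The island at ISL1 scored only 2.29, and an island of the other library lay 3.45 kb from a gene end. Of 25 chromatin modifiers, 6 were called in both, the Polycomb gene CBX2 in the library labelled Vc− alone and KDM6B, which encodes an H3K27 demethylase, in the library labelled Vc+ alone. At CBX2 an island of the other library lay just outside the 1 kb window, so this call differed little between the libraries. The island at KDM6B lay at the higher-coordinate end of the gene. Without strand it cannot be told whether that end holds the promoter. Of 25 TGF-β, BMP and WNT genes, 8 were called in both, NOG in the library labelled Vc− alone and TGFB2 in the library labelled Vc+ alone. No H3K27me3 island was called at any of 15 housekeeping genes in either condition. For H3K27me3, 2 of 23 lists had a net number that fewer than 5% of random lists reached, the blood regulators and the endothelial genes. For H3K4me3, 0 did. Among 23 lists some can fall below 5% by chance alone. HHEX and VWF count towards these nets, although an island of the other library lay just outside the window. In the alternatives run, the net of the blood regulators lay between 3 and 5. The endothelial net stayed at 3, except at gene ends with H3K4me3 in both conditions, where it was 1. Random shares were not recomputed for these alternatives. For H3K4me3 the 4 blood and endothelial lists together had 6 genes in the library labelled Vc+ alone and 2 in the library labelled Vc− alone. This net of 4 was reached by 1.64% of random lists. These lists were joined after their values were seen and no equal-length version was run for H3K4me3, so no direction was read from this net.

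Over all 19974 protein-coding genes, H3K27me3 was called at 3056 (15.3%) in the library labelled Vc− and at 3338 (16.7%) in the library labelled Vc+. A total of 2755 genes were called in both, 301 in the library labelled Vc− alone and 583 in the library labelled Vc+ alone. The latter made up 66.0% of the 884 genes called in 1 library (exact 95% interval 62.7 to 69.1, counting error only, with neighbouring genes not independent). Where no island within 10 kb of a gene end was allowed in the other library, 185 and 387 genes were left. In an alternative chosen after seeing the data, the longer Vc+ list was cut, lowest scores first, to the covered length of the other. The counts were then 337 and 496.

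**Figure D3:**
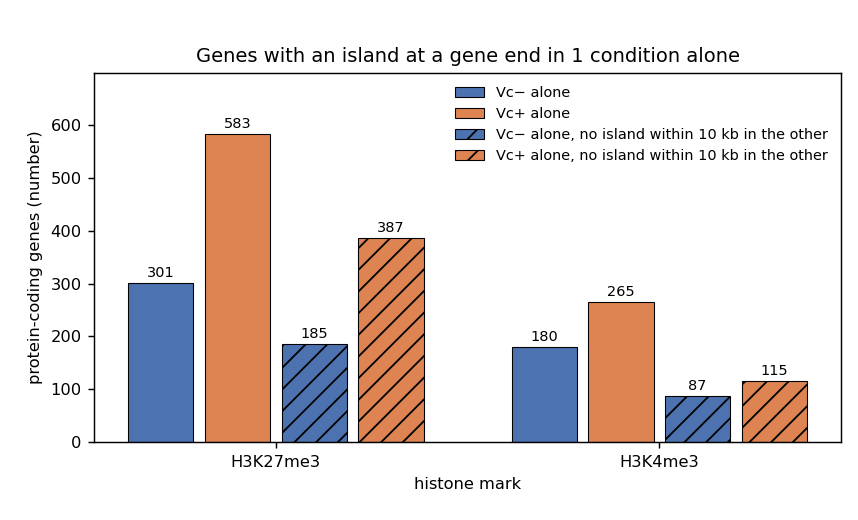
Number of protein-coding genes (vertical axis) with an island within 1 kb of a gene end in 1 condition alone, for each mark; hatched bars count those with no island of the mark within 10 kb in the other condition. For H3K27me3 the bars stand at 301 and 583, and for H3K4me3 at 180 and 265.

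Among genes with no island of the mark within 10 kb of a gene end in the other library, the highest-scoring H3K27me3 islands in the library labelled Vc+ alone lay at DCAF12L1 (score 48.5), LOC102723996 (46.0), B3GNT7 (39.3) and BCL2 (36.3), the last an inhibitor of apoptosis. These were followed by HLA-B, which encodes a class I antigen-presenting molecule (35.3), MISP3 (34.0), DUSP8, a MAP kinase phosphatase (33.5), CLDN23 (30.6), ZFP92 (28.5), NPR1, a natriuretic peptide receptor (27.4), BNIP3, a mitophagy receptor (27.4), and SOX18 (27.4). LOC102723996 (chromosome 21, 5022531 to 5046683) lies within 5 Mb of the largest gene-free gap of its chromosome. The island at BCL2 spanned 4.20 kb at chromosome 18, 63315401 to 63319600, at the higher-coordinate end of the gene, with no island of the other library within 525 kb of a gene end. At HLA-B (chromosome 6, 31353875 to 31357179) the H3K27me3 island was 3.80 kb wide and H3K4me3 was called in the library labelled Vc− alone, and the calls at DUSP8 differed in the same way. Under the same limit of 10 kb, the highest-scoring islands in the library labelled Vc− alone lay at CERS1, GDF1 and UPF1, which share 1 island (42.9), PDZD4 (36.4), TTYH1 and LOC124904770 (33.3), DENND3 (25.5), TENM1 (25.1) and TOX2 (23.6). POLD1 and SPIB (22.5), the homeobox gene MSX2 (22.0), ARHGAP23 (22.0), NCAM2, a neural cell adhesion molecule (21.8), CHRNA4 (21.8) and ZNF439 (20.3) came next.

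H3K4me3 was called at 14050 genes (70.3%) in the library labelled Vc− and at 14135 (70.8%) in the library labelled Vc+, with 13870 called in both, 180 in the library labelled Vc− alone and 265 in the library labelled Vc+ alone. Among blood regulators, CBFA2T3, a transcriptional corepressor, and ZFPM1, a cofactor of GATA1, were called in the library labelled Vc+ alone and NFE2, an erythroid and megakaryocyte factor, in the library labelled Vc− alone, while 20 of 26 were called in both. Among blood cell markers FCER1G and LAPTM5 were called in the library labelled Vc+ alone and TYROBP in the library labelled Vc− alone, with 7 of 24 in both. VWF, with an island of 2.20 kb, was the endothelial gene called in the library labelled Vc+ alone, beside 18 of 20 in both, and NOTCH4 the arterial gene, beside 18 of 19. In the library labelled Vc+ the scores of these islands were 27.6 at NOTCH4, 20.4 at LAPTM5, 9.49 at VWF, 7.42 at FCER1G and 7.05 at CBFA2T3, and in the library labelled Vc− 15.4 at TYROBP and 7.98 at NFE2. The island at ZFPM1, with a score of 143 in the library labelled Vc+, stood against an island of the other library 1.03 kb from a gene end.

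Among genes with no H3K4me3 island within 10 kb of a gene end in the other library, the highest-scoring islands in the library labelled Vc+ alone lay at CAMK2B, which encodes a calmodulin-dependent kinase (45.2), TCFL5 (41.6), PDE1C (34.0), DPP6 (30.9), ONECUT3 (28.8) and HLA-E (27.6). GPSM3 and NOTCH4 (27.6), EEF1A2 (26.8), CDC42EP5 and LENG9 (26.3), MEIOC (26.2), LOXL4 (26.0) and PCSK2 (25.4) followed. In the library labelled Vc− alone they lay at DENND2D (45.2), TYR, which encodes tyrosinase (40.9), SNX20 (34.4), TIMP4 (30.2), C3orf62 (29.9), SMIM10 (28.8) and IGSF1 (28.2), followed by MYO7A (27.3), MRGPRF (26.2), CIMIP2C (25.7), KCNE5 (25.7) and GKN2 (24.8). In the other lists, UTF1, a pluripotency factor, was called in the library labelled Vc+ alone with 8 of 14 in both, COL3A1 of the mesenchymal list in the library labelled Vc− alone with 16 of 22 in both, and SIX3 and NEUROD1 of the neural list in opposite libraries with 21 of 23 in both. The cardiac list had 10 of 15 in both, the endoderm list 8 of 14, the chromatin modifiers 24 of 25, the vitamin C handling list 10 of 12, the TGF-β, BMP and WNT list 24 of 25, the venous and lymphatic list 8 of 9 and the housekeeping list 15 of 15, each with none in 1 condition alone. The excess of calls in the library labelled Vc+ turned round for this mark when its longer list was cut to the covered length of the other. Genes in Vc− alone against Vc+ alone were then 280 against 190 by score per kb and 368 against 144 by score. No direction was therefore read from this excess.

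Next, both marks were read at each gene. In the library pair labelled Vc−, 2676 genes (13.4%) carried both marks, 11374 (56.9%) H3K4me3 alone, 380 (1.90%) H3K27me3 alone and 5544 (27.8%) neither. In the pair labelled Vc+ these numbers were 2997 (15%), 11138 (55.8%), 341 (1.71%) and 5498 (27.5%). A total of 458 genes had H3K4me3 alone by the Vc− lists and both marks by the Vc+ lists, among them IKZF1, MYB, LYL1, HHEX, SOX18, CDH5, CD34 and HEY1. A total of 233 went the other way, among them MSX2, TENM1, NCAM2, NOG and CBX2. Of the 583 genes with H3K27me3 in the library labelled Vc+ alone, 78.6% (exact 95% interval 75 to 81.8) carried H3K4me3 in both conditions. The share was 77.4% (72.3 to 82.0) of the 301 in the library labelled Vc− alone. It was 87.7% (86.4 to 88.9) of the 2755 with H3K27me3 in both conditions, and 69.4% (68.8 to 70.1) of all genes. The marks could sit at opposite ends of a gene, as at VWF and, among the 458 genes, at CDH5. They shared an end at 2551 genes in the pair labelled Vc− and 2859 in the pair labelled Vc+.

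GATA2 and RUNX1, the latter the main transcription factor of the endothelial to blood transition, were read in all 4 libraries. At GATA2 (gene 2624, chromosome 3, 128479422 to 128493201) the H3K27me3 island at the higher-coordinate end was 2.40 kb wide in the library labelled Vc− (128491201 to 128493600) and 4.20 kb in the library labelled Vc+ (128490801 to 128495000). The H3K4me3 island at GATA2 was 11.8 kb and 12 kb wide. No island of either mark lay within 1 kb of an end of RUNX1 (gene 861, chromosome 21, 34787801 to 35049302) in any library. Inside RUNX1, H3K27me3 covered 14 kb in 3 islands in the library labelled Vc− and 12 kb in 2 islands in the library labelled Vc+, between 34882601 and 34901200. An H3K4me3 island of 10.2 kb in the first and 10.6 kb in the second overlapped that region, and the library labelled Vc+ had a further H3K4me3 island of 1.60 kb at 34845401 to 34847000.

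The HOX clusters held the widest H3K27me3 islands in both conditions. The HOXC island was 153 kb wide in the library labelled Vc− (chromosome 12, 53916201 to 54069000) and 219 kb in the library labelled Vc+ (53922201 to 54140800), and the HOXA islands were 143 kb and 142 kb wide. At HOXD an island of 132 kb in the library labelled Vc+ stood against 2 islands in the other, the wider of 77.2 kb. The covered length at HOXD was not compared. Both libraries also held a wide island without a gene end on chromosome 1, which was 92.4 kb (143184601 to 143277000) in the library labelled Vc− and 92.2 kb in the library labelled Vc+. That stretch lay within 5 Mb of the largest gene-free gap of the chromosome. H3K4me3 islands of 66 kb (Vc−) and 91.4 kb (Vc+) overlapped it, so it was not particular to H3K27me3. The longer HOXC island joined stretches called apart in the other library, since over a region of 259 kb H3K27me3 covered 229 kb in 12 islands and 232 kb in 6 islands. H3K4me3 covered 7.60 kb in 6 islands and 18.8 kb in 15 islands of the same region, and HOXC8 and HOXC10 were called for H3K4me3 in the library labelled Vc+ alone. Of 39 HOX genes 34 carried H3K27me3 in both conditions, HOXB4 and HOXB8 in the library labelled Vc+ alone, and HOXB2, HOXB3 and HOXB5 in neither. An island of the other library lay 1.05 kb from an end of HOXB4, just outside the window. The widest H3K4me3 islands, up to 73.6 kb and 91.4 kb, held no gene end of a protein-coding gene and lay within 5 Mb of the largest gene-free gap of chromosomes 1, 4 and 10.

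**Figure D4:**
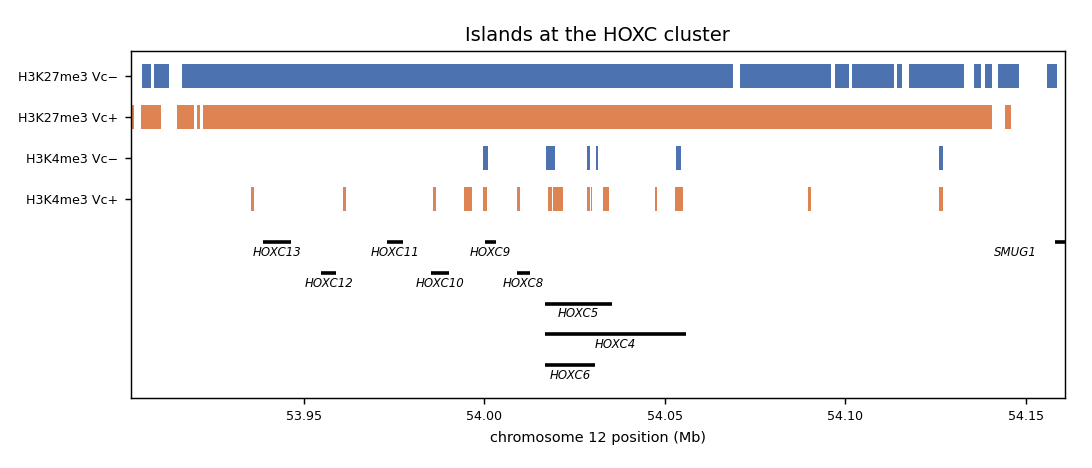
Islands of both marks in both conditions (colour) over the HOXC cluster on chromosome 12, drawn to scale against the position in Mb, with protein-coding genes as black bars. H3K27me3 forms 1 island of 219 kb in the library labelled Vc+ where the library labelled Vc− has an island of 153 kb followed by shorter ones, and H3K4me3 has 15 islands against 6.

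Islands of both marks were wider in the libraries labelled Vc+. H3K27me3 islands covered 40.6 Mb in the library labelled Vc− and 51.7 Mb in the library labelled Vc+, a ratio of 1.27, with median widths of 3200 and 4000 bp. H3K4me3 islands covered 43.3 and 48.2 Mb, a ratio of 1.11, with median widths of 1600 and 1800 bp. Of H3K27me3 islands, 71.8% (exact 95% interval 70.8 to 72.7) in the library labelled Vc− and 63.0% (62.0 to 64.0) in the library labelled Vc+ overlapped an island of the other list, and of H3K4me3 islands 88.5% (88.1 to 88.9) and 88.4% (88.0 to 88.8). The Jaccard index in base pairs was 0.469 for H3K27me3 and 0.690 for H3K4me3. H3K27me3 islands without a partner were shorter and lower in score, with a median score of 4.63 in the library labelled Vc− and 5.41 in the library labelled Vc+, against 17.5 and 20.7 for islands with a partner. Over 4901 H3K27me3 islands that matched exactly 1 island in each direction, the median width ratio of Vc+ over Vc− was 1.17 and 64.7% were wider in the library labelled Vc+. For 18432 such H3K4me3 islands the ratio was 1.08 and 54.1% were wider.

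**Figure D5:**
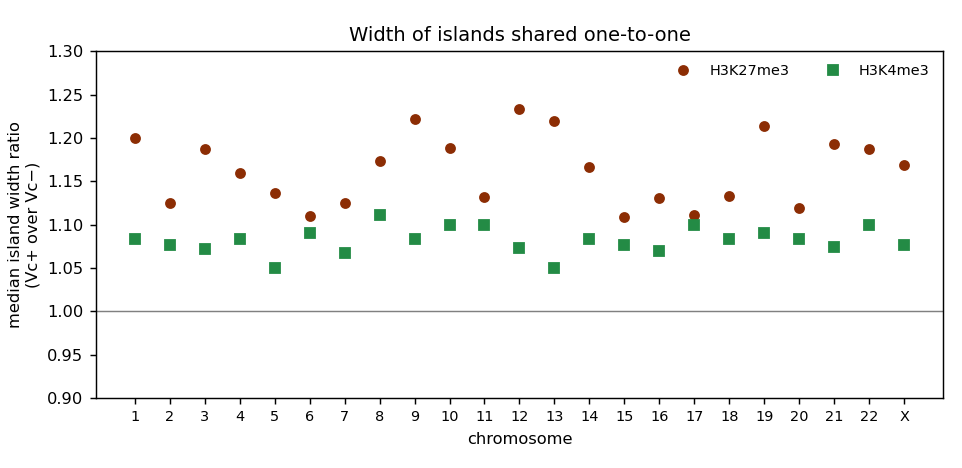
Median width ratio (vertical axis, Vc+ over Vc−, axis not starting at 0) of islands that matched exactly 1 island in the other list, for each chromosome (horizontal axis) and mark. All 23 chromosomes lie above 1 for both marks, between 1.11 and 1.23 for H3K27me3 and between 1.05 and 1.11 for H3K4me3.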

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

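Of 174 alternative values, 108 stayed within the limits set for the main value (its counting interval, or 1.5 times a count), 63 moved beyond them and 3 turned direction. The interval of the covered length ratio is borrowed from the number of islands. Alternatives chosen after the data were seen are leaving out islands near gene-free gaps, equal covered length by score, a score of at least 10 and the choices of gene end. No paired analysis was possible because each group has 1 library. Not run were reads in regions called in both lists, annotated transcript starts and CpG matching. The excess of H3K27me3 calls in the library labelled Vc+ over all genes (282) stayed positive in all 11 alternatives run, lowest at 159 with equal covered length by score. Over the 4 blood and endothelial lists the net of 10 lay between 7 and 10 in the 6 run. Its members changed: UNC5B was called in Vc− alone with equal covered length by score and with a score of at least 10, where MECOM entered Vc+ alone and CD33 and CD34 left, and in the window of 2 kb HHEX and VWF left and SOX7 entered. Unknown depth limits all counts, since a deeper library gives more and wider islands.

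For H3K4me3 genes, the net of 85 turned to -90 with equal covered length by score per kb (280 in Vc− alone) and to -224 by score (368 against 144), because the longer list was shortened to the length of the other. Among the upper 50% of islands by score per kb it was 51 (1424 against 1475), with 50% of the window covered 302 (331 against 633), and with no island allowed within 10 kb 28 (87 against 115). The H3K27me3 counts for the upper 50% were 286 and 543, and with 50% of the window covered 244 and 655, so under these settings H3K4me3 differed at more genes than H3K27me3, where the main counts have fewer. With long non-coding RNA genes the H3K4me3 counts were 362 and 461. For H3K27me3 genes, long non-coding RNA genes gave 951 in Vc+ alone and a net of 530, no island within 10 kb gave 185 and 387, and the gene end with H3K4me3, over 12466 genes with 1 such end, gave 171 and 361. The cause of these moves was not tested. Genes with both marks numbered 992 and 1347 among the upper 50% of islands.

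The ratio of H3K4me3 island numbers turned from 0.986 to 1.05 among islands of at least 1 kb, and the cause was not tested. The H3K4me3 covered length ratio was 1.14 there and 1.08 among the upper 50%, and the H3K27me3 ratio 1.31 away from gene-free gaps. Shares of islands with a partner are lower by construction where 50% of an island must be covered, and the cause of the other moves was not tested. Given as H3K27me3 in Vc− and Vc+, then H3K4me3 in Vc− and Vc+, they were 66.1, 51.2, 87.1 and 85.2% with 50% of the island covered, and 47.3, 44.1, 80.9 and 82.1% with 50% reciprocal overlap. They were 79.0, 70.8, 79.6 and 80.6% between the upper 50% of both lists, 88.8, 83.6, 99.1 and 99.5% for the upper 50% against the whole other list, 67.6, 64.2, 89.2 and 87.9% with equal island numbers, and 81.4, 67.0, 90.8 and 90.6% away from gene-free gaps.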

Other observations

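Genes of the class I antigen presentation pathway, chosen after their values were seen, were called differently between the libraries. HLA-B had H3K4me3 alone by the lists labelled Vc− and H3K27me3 alone by those labelled Vc+, and HLA-C had H3K4me3 alone and then neither mark. HLA-E, TAP1 and PSMB9 had neither mark and then H3K4me3 alone, and HLA-G had H3K27me3 alone and then neither. Reads from the HLA genes, which are similar to each other, can map to more than 1 of them. How such reads were treated is not given in the sources used here. Of 477 zinc finger genes by symbol, 24 carried H3K27me3 in both conditions, 21 in the library labelled Vc− alone and 32 in the library labelled Vc+ alone, so that most of the marked members were called in 1 library. H3K4me3 was called at 413 of them in both, with ZNF574 and ZNF30 in Vc− alone and ZNF621 and ZNF366 in Vc+ alone. The highest H3K27me3 scores among these differing members were at ZNF543 (54.6) and ZNF850 (23.9) within the library labelled Vc+ and at ZNF692 (40.1) within the library labelled Vc−, with islands of the other library 1.47, 4.52 and 1.32 kb from a gene end.

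Other families named by symbol gave these H3K27me3 counts, as called in both, in Vc− alone and in Vc+ alone. The FOX family of 46 genes had 26, 1 (FOXH1) and 2 (FOXP1 and FOXK1), the SOX family of 19 had 9, 0 and 1 (SOX18), the TBX family of 13 had 7, 0 and 0, and the WNT family of 19 had 12, 0 and 0. Among 53 clustered protocadherins 1 was called in both and 2 (PCDHAC1 and PCDHGC3) in Vc+ alone, while 41 carried H3K4me3 in both, PCDHB13 in Vc− alone, and PCDHB8 and PCDHB14 in Vc+ alone. Of 55 keratins 5 were called in both and 1 (KRT25) in Vc− alone, and of 392 olfactory receptors 4 in both and 1 in each condition alone. For H3K4me3, FOX genes were called in both at 39, SOX genes at 17 with SOX15 in Vc− alone, TBX genes at 10 with TBX1 in Vc+ alone, WNT genes at 13 with WNT2B in Vc− alone, and HOX genes at 32. Keratins were called at 6 with KRT7 in Vc+ alone, and olfactory receptors at 6 with OR4D9 in Vc+ alone. Around the largest gene-free gap of each chromosome, within 5 Mb, lay 35.4% of H3K27me3 islands in the library labelled Vc− and 30.5% in the library labelled Vc+, with median scores of 4.46 and 4.59, against 18.3 and 15.8 elsewhere. Of H3K4me3 islands 10.4% and 10.3% lay there.

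The tests of another cell type and of the labels were chosen after the values they rest on had been seen. The all-gene counts with equal covered length, and the 10 genes themselves, had also been seen before the remaining tests were written. H3K27me3 at 10 blood and endothelial genes in the library labelled Vc+ alone may be a property of those cells. The longer covered length of that list stays open as a cause. With equal covered length by score the net over the 4 lists was 7, from 8 genes in Vc+ alone (without CD33 and CD34) and UNC5B in Vc− alone. That trimming took the lowest-scoring islands out of the list labelled Vc+ only, and the islands at these 8 genes scored 13.1 (LYL1) to 31.7 (VWF). Since the score itself depends on depth and island width, their staying could not decide the question. A general excess of such calls at genes with H3K4me3 stays open: the joined lists stood at 0.04% of random lists drawn from such genes, but they were joined after their values were seen, and of the lists fixed before only the blood regulators were low (0.34%), against 9.16, 19.7 and 36.2% for the others. Cells of another type stay open: the net number of H3K4me3 calls was 0 over the 5 other-lineage lists and 4 over the blood and endothelial lists, and most of these genes carry H3K4me3 in both conditions, which would hide a small share of other cells. Exchanged condition labels stay open too, since 4 of 4 file names contradict the labels and no value in an island list marks the condition, so an effect of vitamin C, as named by the design, is untested in size and in direction. As labelled, the excess of H3K27me3 calls in Vc+ runs against the demethylation named in the title, and by the file names it would run with it. That alone cannot decide which assignment is right.

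The test of breadth shared by both marks was chosen after the widths had been seen. Islands of both marks were wider in the libraries labelled Vc+. A library-wide difference in breadth, as depth or the size of DNA fragments could give, would put the median width ratio above 1 on most chromosomes. It was above 1 on 23 of 23 for each mark. Given the overall median ratios of 1.17 and 1.08 such a count was likely from the start. A biological spread would give it too, so the count cannot tell these apart. H3K4me3 islands at housekeeping genes had a median ratio of 1.09, with 9 of 16 wider. Islands within 5 Mb of the gene-free gaps are argued against as the sole cause, since away from them the H3K27me3 ratio was 1.15. These gaps stand in for centromeres and leave some dense stretches of low-scoring islands in. On chromosome 21, 10 to 15 Mb, mostly outside that limit, held 132 H3K27me3 islands in Vc− and 112 in Vc+, with a median score of 4.41 in each. Centromeric islands beyond the limit were not tested. Depth, fragment size and a biological spread of the marks with the condition stay open, because read counts were not used here.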
